A study of Bombyx mori with 9 samples.

How the data were processed

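The libraries come from silkworm BmN4 cells. Per the labels' protocols, PIWI complexes were isolated with an antibody to a DDDDK tag or to Ago3, libraries were made with a small RNA kit for sequencing on a MiSeq, and the submitters' processing notes name cutadapt, Bowtie and Bowtie2 without versions or roles. The genome build, element library and mapping settings are not given in the sources used here. The deposited Siwi table gives each distinct sequence of 22 to 32 nt in RPM for 6 libraries, scaled over the sequences listed. The deposited table of Ago3-bound RNA, which the labels assign to the Ago3_piRNA sample, gives RPM for sequences of 4 to 44 nt, and its name also carries the control knockdown and element mapping, so it may be limited to RNAs that match elements. The 2 RPM tables may therefore cover different kinds of sequence. The third deposited table gives each of 121 transposable elements as a percent of Target_L and of Target_S. The authors' rule for assigning short RNA to elements is not given there. The table holds 1 further column of values that names no single sample, which was not used.

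In the RPM tables nearly all values were whole multiples of the value of 1 read, within 0.05 reads (99.99896% in siAgo3 replicate 2, the lowest), so whole reads were recovered. Totals ran from 607274 to 2685685 reads in the Siwi libraries and were 407838 in the Ago3_piRNA library. The 1 read of siAgo3 replicate 2 is worth 1.65 RPM, against 0.372 RPM in siLuc replicate 1, so low values are least precise there. Replicates of each group differed by more than sampling noise (chi-square per degree of freedom 2.31 in siLuc, 1.24 in siAgo3 and 1.65 in siVret) and were counted as separate. Their log2 values correlated at 0.935, 0.868 and 0.892.

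Sequences with a mean of at least 5 RPM over the 6 Siwi libraries (21512, holding 62.2 to 71.2% of RPM) were tested with limma 3.58.1 in R 4.3.3 on log2(RPM + 1), with a trend and 1 fit over the 3 groups, and Benjamini-Hochberg adjustment at 0.05. Fold changes on that scale understate the change of low sequences. For a sequence with no read in a group, the fold is given against a floor of 3 reads over that group's libraries. The 4 classes by the base at positions 1 and 10 and the 4 by length, were tested with camera (preset correlation 0.01, and an estimated one) and with fry, over 24 tests. Sets added later (tRNA fragments, sequences with an Ago3-bound partner at any level or at 20 RPM, and sequences identical to an Ago3-bound one of at least 20 RPM) were adjusted among themselves over 12 tests. The set of identical sequences was not called by camera in any comparison (adjusted p of 0.064 or more), and fry called it lower in siAgo3 against siLuc (adjusted p = 0.0405) and higher in siVret against siAgo3 (adjusted p = 0.00952). Fry was run on RPM only and does not compare a class with other sequences, so its calls can follow a scaling shift of all sequences. Shares and mean lengths are weighted by RPM and compared with exact 2-sided permutation tests, which with 2 libraries against 2 cannot go below 0.333. Shares in the Ago3_piRNA library carry 95% Wilson intervals from recovered reads. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

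RNAs were grouped into families by their first 20 nt, and the mean length of families with a mean of at least 50 RPM was compared with limma. Family abundance uses the limma fit on RPM summed per family. The families named are among the 15 most abundant and were chosen after their values were seen. The single sequences named follow a rule fixed before the data were examined, as were the classes above. For each comparison it takes the 10 largest rises and the 10 largest falls past the threshold whose replicates do not overlap, the 5 sequences most abundant in siLuc, and the 10 highest features of each Ago3 library. With 2 libraries against 2, chance gives 33.3% of features without overlap. The text gives a selection of them. Fragments of tRNA were recognised by sequence likeness, since no tRNA annotation was used. Elements were assigned to LTR, non-LTR, SINE or DNA classes by words in their names, and a name that states LTR or non-LTR decided where several words applied.

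The correlation of fold changes was set beside 100 simulations of unchanged groups against the same controls. On simulated data built from the siAgo3 and siLuc comparison (21512 sequences), the limma step recovered 15 of 100 sequences changed 2-fold and 59 of 100 changed 4-fold, with 1 false call. The search for 10-nt partners found 308 for 300 planted and at most 17 at any other overlap. Planned comparisons by transposable element in the Siwi libraries, and overlap by genome position, were not made because no table used here pairs sequences with elements or positions. Alternatives covered the pseudocount (0.5 and 5), the filter (none, 20 RPM), scaling (median-of-ratios, TMM), a replicate block, fits of 2 groups, lengths of 24 to 32 nt, merging by the first 20 nt, edgeR 4.0.16 quasi-likelihood tests on the recovered reads, leaving out each library, and, chosen later, leaving out tRNA fragments and giving each knockdown its own siLuc library. The edgeR test called 6777, 9181 and 5539 sequences in siAgo3 against siLuc, siVret against siLuc and siVret against siAgo3. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.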

Results

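Small RNAs bound to PIWI proteins were sequenced from BmN4, a cell line derived from silkworm (Bombyx mori) ovary that carries a germline piRNA pathway. PIWI proteins hold piRNAs, small guide RNAs directed mostly at transposable elements. BmN4 cells express a pair of them, Siwi and Ago3, which in the ping-pong cycle cut complementary transcripts in alternation, so that the guides they carry overlap by 10 nt at their 5′ ends. The 9 libraries form 6 groups. Siwi-bound piRNAs were collected after knockdown with siLuc, used here as the control, after knockdown of Ago3 (siAgo3) and after knockdown of Vret (siVret; Vreteno, a Tudor-domain protein of the piRNA pathway), with 2 libraries per group. One library each holds Ago3-bound piRNAs (Ago3_piRNA), RNA of 30 to 100 nt from the Ago3 complex (Target_L) and RNA of about 16 nt from it (Target_S). The Siwi table lists 1123691 distinct sequences of 22 to 32 nt. The siLuc libraries held 2685685 and 1865889 reads, the siAgo3 libraries 2186429 and 607274, the siVret libraries 1018586 and 1281688, and the Ago3_piRNA library 407838. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The tables list small RNA and not the mRNAs of Ago3 or Vret, so the depletion of either target could not be checked.

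In control cells, Siwi held mainly RNAs of 28 and 29 nt that began with U. The share of RPM that began with U was 81.0% ± 0.598 (SD, n = 2), the share with A at position 10 was 32.2% ± 0.121, and mean length was 28.1 nt ± 0.0684. The most abundant sequences were 3 fragments of the 5′ part of tRNA-Asp, of which TCTTCGGTAGTATAGTGGTCAGTATCCCC reached 24345 RPM ± 1395. Behind them came AACTCAAGACACAAGATCGCGACGGCAGC at 6161 RPM ± 1222 and TCGAAGAAGAGGGCTCCTGTCGGAATGG at 4289 RPM ± 1213. The tables pair no sequence with a gene, element or genome position, so sequences are identified by their bases and, for the tRNA fragments and microRNAs, by likeness to known RNAs.

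The comparison of siAgo3 with siLuc asked how the Siwi-bound pool changed when the partner PIWI protein was depleted. Long Siwi-bound RNAs were lower in siAgo3 and tRNA fragments were higher, while abundant piRNA families went both ways. The family of RNAs that share the 5′ end AACGATCGCAGACGGTCGAA went from 5474 RPM ± 248 to 1714 ± 105, a log2 fold change of -1.68 ± 0.0850 (SE, adjusted p = 1.883e-10). The family starting with TCGAAGAAGAGGGCTCCTGT went from 12579 RPM ± 1756 to 4794 ± 184, a log2 fold change of -1.39 ± 0.0967 (adjusted p = 9.393e-09). The family starting with TGATCTCAGCGGGGGGTTAG rose from 2332 RPM ± 366 to 4037 ± 187, a log2 fold change of 0.80 ± 0.0985 (adjusted p = 8.664e-06), and TGACTGCAAAATAGGTGATT rose by 0.27 ± 0.0797 (adjusted p = 0.0186). Among single sequences, 9 of the 10 largest falls were RNAs of 31 or 32 nt. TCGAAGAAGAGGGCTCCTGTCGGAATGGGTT, a 31-nt member of that family, fell from 161 RPM ± 11.8 to 0.457 ± 0.647, and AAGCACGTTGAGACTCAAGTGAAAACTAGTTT, of 32 nt, fell from 351 RPM ± 33.6 to 9.33 ± 5.43 (adjusted p = 4.124e-10 and 3.215e-10). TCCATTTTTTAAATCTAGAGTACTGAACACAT went from 36.3 RPM ± 9.70 to no read in either siAgo3 library, at least 33.8-fold lower against a floor of 3 reads over the group. The exception in length was TACATTATGATCGGTCAGGTAGATC, of 25 nt, at 76.7 RPM ± 12.1 in siLuc and 2.06 ± 2.91 in siAgo3.

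The 10 largest rises in siAgo3 were sequences of 22 to 29 nt that were at or near 0 in siLuc and low in siVret. TAAAATATAATCTGGAGAACACT stood at 55.3 RPM ± 21.9 in siAgo3 and had no read in siLuc, at least 83.9-fold higher, with 0.982 RPM ± 1.39 in siVret. ACAAACTTAAAACTAGAACAGGCT was at 38.2 RPM ± 4.21, at least 57.9-fold higher than siLuc. TGGTTGTTAAAAAAGAACTCGTGGT was at 43.9 RPM ± 8.47 against 0.186 ± 0.263 in siLuc, a log2 fold change of 5.25 ± 0.667 (adjusted p = 4.559e-06). The rises fell into a few overlapping families, and the origin of these sequences is not assigned in the tables. Of the 5 sequences most abundant in control cells, the 3 tRNA-Asp fragments rose by 1.33, 1.46 and 1.72 on the log2 scale, while AACTCAAGACACAAGATCGCGACGGCAGC fell by 0.57 and TCGAAGAAGAGGGCTCCTGTCGGAATGG fell by 0.92 (all with an adjusted p of 0.0008873 or less).

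Across 21512 sequences tested with limma on log2(RPM + 1), 5344 passed an adjusted p of 0.05 in siAgo3 against siLuc, 1669 higher and 3675 lower. By the length classes, RNAs of 29 nt and over fell as a set, with 2330 of 7826 lower and 250 higher (2495 and 290 when adjusted over the list alone) and a median log2 fold change of -0.57. Those of 24 to 26 nt had 380 higher and 196 lower of 2749 (356 and 182 adjusted over the list alone), and their median was 0.20. The set test with a preset correlation, adjusted over 24 tests, called all 4 length classes (adjusted p = 2.4075e-11 for the longest), and fry called the longest lower (adjusted p = 0.0151). With an estimated correlation none passed (adjusted p = 0.083 for the longest and for 27 to 28 nt, 0.42 for 24 to 26 nt and 0.82 for under 24 nt). The call of RNAs under 24 nt was lost without siAgo3 replicate 2. Of the 4 classes by base at positions 1 and 10, camera called none against other sequences (adjusted p of 0.55 or more), while fry, which asks whether a class moved at all, called 3 lower (adjusted p = 0.0216 for each class with U first and 0.0427 for other first bases with A at position 10). Fry was run on RPM only. The medians of these 3 classes (-0.12, -0.18 and -0.16) lay near that of all sequences on RPM, so these calls may reflect scaling. The share of higher calls depended on scaling, since tRNA fragments took a larger share of RPM in siAgo3. It was 31.2% on RPM, 41.9% with median-of-ratios factors, 45.8% with TMM factors and 42.5% without tRNA fragments. The median log2 fold change of all sequences was -0.15 on RPM, -0.02 with median-of-ratios and 0.02 with TMM. Without siLuc replicate 1, siLuc replicate 2 or siAgo3 replicate 2, the count of calls was 2213, 2283 or 3335.

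Depletion of Vret was compared with siLuc to ask which Siwi-bound RNAs moved when this Tudor-domain protein was reduced. The largest falls in siVret were again RNAs of 30 to 32 nt. The 10 largest rises, most of them starting with A, shared no sequence with the 10 largest of siAgo3. Most of them nevertheless had a higher mean in siAgo3 than in siLuc. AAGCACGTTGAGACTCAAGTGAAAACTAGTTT went from 351 RPM ± 33.6 in siLuc to 2.25 ± 0.979 in siVret, a log2 fold change of -6.79 ± 0.350 (adjusted p = 4.906e-12). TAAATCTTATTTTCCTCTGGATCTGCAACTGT went from 45.5 RPM ± 10.5 to no read, at least 34.9-fold lower. The family starting with TCGAAGAAGAGGGCTCCTGT dropped to 2663 RPM ± 329, a log2 fold change of -2.24 ± 0.0967. In contrast to siAgo3, the AACGATCGCAGACGGTCGAA family stood at 5409 RPM ± 408 in siVret, a log2 fold change of -0.02 ± 0.0850 from siLuc (adjusted p = 0.8885).

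The largest rises in siVret came from overlapping families. AAGGGAGATATGGTTCGGAACGCGA went from 0.722 RPM ± 0.495 to 57.1 ± 25.2 and its 28-nt form AAGGGAGATATGGTTCGGAACGCGAAGA from 0.722 ± 0.495 to 48.9 ± 13.6. TTAGTGACGCGCATGAATGGATT rose from 9.19 RPM ± 1.41 to 178 ± 50.5, and ATTTAATATCGACGACGACGACGGTGC from 5.76 ± 1.33 to 145 ± 4.97 (log2 fold changes of 4.11 ± 0.300 and 4.44 ± 0.277, adjusted p = 9.25e-10 and 8.231e-11). AGACTTGCCTGTCGAATATCTGACGCT rose from 4.54 RPM ± 1.16 to 96.5 ± 10.7. Among the abundant sequences, the 3 tRNA-Asp fragments rose by 1.02, 1.38 and 1.78 on the log2 scale, AACTCAAGACACAAGATCGCGACGGCAGC fell by 1.01 and TCGAAGAAGAGGGCTCCTGTCGGAATGG fell by 2.15.

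In siVret against siLuc, 7724 of the 21512 sequences passed, 3489 higher and 4235 lower. The balance turned to 4172 higher and 3786 lower without tRNA fragments, and to 1632 and 1532 at a mean of at least 20 RPM, so no overall direction held. RNAs of 29 nt and over had 2469 lower and 648 higher of 7826 (2523 and 677 adjusted over the list alone) with a median of -0.52, and those of 27 to 28 nt had 2104 higher and 1379 lower of 10470 (2037 and 1341 adjusted over the list alone) with a median of 0.18. The preset-correlation test called these and the 24 to 26 nt class (adjusted p = 2.0677e-09, 0.00031331 and 0.0015606), and with an estimated correlation none passed (adjusted p = 0.083, 0.083 and 0.52). Here too fry called the longest class lower (adjusted p = 0.0154). RNAs with neither U at position 1 nor A at position 10 had 531 higher and 347 lower of 2050 (median 0.13), which did not pass camera (adjusted p = 0.084 with the preset correlation and 0.16 with an estimated correlation) but passed fry as higher (adjusted p = 0.0216), and passed camera too when only sequences with a mean of at least 20 RPM were kept. Fry also called RNAs with U first and A at position 10 lower (adjusted p = 0.0347). Their median was -0.09 against -0.06 for all sequences, so this call may reflect scaling too. Without siLuc replicate 1 or 2 the count of calls was 4040 or 4126.

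The comparison of siVret with siAgo3 asked where the knockdowns differed from each other. Several abundant families were higher in siVret. The AACGATCGCAGACGGTCGAA family was 1.66 ± 0.0850 higher on the log2 scale (adjusted p = 4.607e-10), and ACAAAGAACGGCTTACTGTA and TAGAAACACACTAAACGACC, families at 3357 RPM ± 35.8 and 3320 ± 43.4 in siVret, were higher by 0.79 ± 0.0851 and 0.84 ± 0.0853. The family of TCGAAGAAGAGGGCTCCTGT was lower by -0.85 ± 0.0967. TTAGTGACGCGCATGAATGGATT led the rises (6.49 RPM ± 0.130 in siAgo3), and AGAAGAACAAAGAACAGTGGATTATGT stood at 27.6 RPM ± 2.62 against 1.14 ± 1.62. Among the 10 largest falls, 8 were sequences that also led the rises of siAgo3 over siLuc, and TCCGAAACTACTGGACCGATTTGAAAA, at 26.1 RPM ± 2.05 in siLuc and 35.3 ± 1.36 in siAgo3, was at 0.881 ± 0.143 in siVret. In all 5546 sequences passed, 3357 higher and 2189 lower in siVret. The share of higher calls was 60.5% on RPM, 50.4% with median-of-ratios and 49.4% with TMM factors, and the median log2 fold change was 0.16, 0.03 and 0.02, so no overall direction held across scalings. Without siAgo3 replicate 2 the count was 3319. Of the length classes, RNAs under 24 nt were called lower (38 higher and 68 lower of 467, and 37 and 67 adjusted over the list alone; adjusted p = 0.040), a call that did not hold with an estimated correlation (adjusted p = 0.91) or without siAgo3 replicate 2 or siVret replicate 1.

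Fold changes of siAgo3 and siVret against the same siLuc libraries were correlated across sequences, which are not independent replicates (Pearson r = 0.596, Spearman rho = 0.565). Simulated unchanged groups against those controls gave r = 0.340, and the covariance was 0.708 against 0.0606 simulated. A total of 1039 sequences were called higher in both knockdowns, where independent lists would share 271, and 1913 were called lower in both, where independent lists would share 723. Only 144 were called in opposite directions. With 1 siLuc library set against each knockdown, a split chosen after the data were seen, r was 0.512 or 0.515 and the covariance 0.643 or 0.645. With 2 controls no split leaves replicates on both sides, so part of the excess in shared calls may come from the shared controls.

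The length of Siwi-bound RNA shifted in both knockdowns. RNAs of 30 to 32 nt made up 14.6% ± 0.681 of RPM in siLuc, 6.11% ± 0.0792 in siAgo3 and 6.92% ± 0.348 in siVret. At 32 nt the share went from 1.31% ± 0.0219 to 0.209% ± 0.00285 and 0.302% ± 0.00187. Shorter RNAs took up more of the pool. Those under 24 nt went from 3.24% ± 0.166 to 6.00% ± 1.30 in siAgo3 and 5.30% ± 1.34 in siVret. Most of that rise was 1 tRNA-Asp fragment of 23 nt. It stood at 10981 RPM ± 435 in siLuc, 30612 ± 6993 in siAgo3 and 29037 ± 6676 in siVret. RNAs of 24 to 26 nt went from 10.8% ± 1.11 to 13.7% ± 3.83e-06 and 13.4% ± 1.14. The fall at 30 to 32 nt held without tRNA fragments (15.3% ± 0.606, 7.10% ± 0.0238 and 7.91% ± 0.389). Mean length was 27.6 nt ± 0.0702 in siAgo3 and 27.6 nt ± 0.123 in siVret, and every knockdown library lay below both siLuc libraries. With 2 libraries per group an exact 2-sided permutation test cannot go below p = 0.333. Each of these differences in share and mean length gave that value in both knockdowns.

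**Figure D1:**
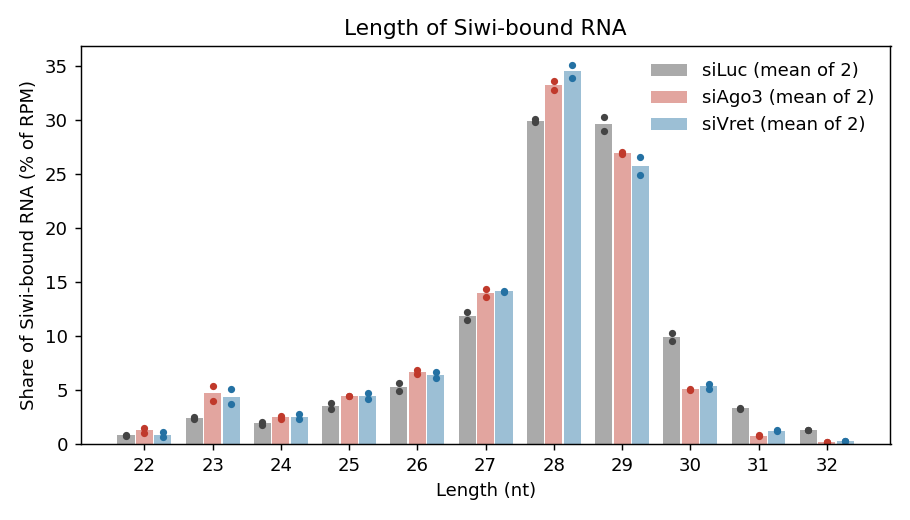
Share of Siwi-bound RNA (percent of RPM, y axis) at each length from 22 to 32 nt (x axis) in siLuc, siAgo3 and siVret. Bars are means of 2 libraries and points are libraries; at 30, 31 and 32 nt every knockdown library lies below both siLuc libraries.

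The shift was also present among RNAs that share their first 20 nt, and so differ at the 3′ end. Of 2373 such families with a mean of at least 50 RPM, 88.4% had a shorter mean length in siAgo3 than in siLuc (median change -0.22 nt) and 82.7% in siVret (median -0.19 nt). Replicates differed by a median of 0.0837 nt in siLuc, 0.114 nt in siAgo3 and 0.103 nt in siVret. With limma on mean length, 643 families were shorter and 18 longer in siAgo3, 520 were shorter and 46 longer in siVret, and no family passed between siVret and siAgo3. The family starting with TATCTAACGTCGAACCGGTC went from 29.1 nt ± 0.232 to 27.9 ± 0.0673 in siAgo3 and 28.2 ± 0.208 in siVret. TCATTACCCTGGACGGTGGA went from 28.3 nt ± 0.131 to 27.6 ± 0.0212 and 27.6 ± 0.0547, while its abundance in siVret rose from 1798 RPM ± 25.2 to 2970 ± 33.4 (adjusted p = 2.776e-06). The abundant family TGACTGCAAAATAGGTGATT kept its length, at 27.96 nt in all 3 groups.

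Differences in base composition depended on whether tRNA fragments were counted. The share of RPM starting with U was 81.1% ± 0.145 in siAgo3 and 80.7% ± 0.446 in siVret, which differed from siLuc by 0.0774 and -0.361 percentage points (permutation p = 1 and 0.667). A at position 10 went from 32.2% ± 0.121 in siLuc to 28.5% ± 0.401 in siAgo3 and 27.97% ± 0.295 in siVret. Left without tRNA fragments, an alternative chosen after the data were seen, the share was 34.2% ± 0.216, 33.6% ± 0.0686 and 32.5% ± 0.380. The share starting with U was then 79.9% ± 0.686, 77.9% ± 0.100 and 77.6% ± 0.551, with every knockdown library below both siLuc libraries (permutation p = 0.333).

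Fragments of tRNA-Asp, the most abundant RNA of the Siwi libraries, rose in both knockdowns. Their sum went from 51382 RPM ± 2635 in siLuc to 139186 ± 9899 in siAgo3 and 127338 ± 1388 in siVret, 2.71-fold and 2.48-fold. Fragments of tRNA-Glu went from 6253 RPM ± 224 to 10497 ± 366 and 12051 ± 346, 1.68-fold and 1.93-fold. Of 31 tested tRNA-fragment sequences, 20 rose and 5 fell in siAgo3, and 23 rose and 2 fell in siVret. As a set chosen after the data were seen, they passed with a preset and with an estimated correlation (adjusted p = 8.4189e-06 and 5.21e-06 with the preset one over 12 tests, and 0.0465 in both comparisons with an estimated correlation). MicroRNAs, which Argonaute proteins other than PIWI carry, served as markers of RNA not bound by Siwi. The 15 listed microRNAs, matched over 20 nt, summed to 90.5 RPM ± 1.48 in siLuc, 210 ± 45.04 in siAgo3 and 157 ± 42.9 in siVret. The bantam sequence on the list differed from that in the libraries at base 20, so it had no match over 20 nt. Matched over 18 nt, bantam was at 515 RPM ± 5.34 in siLuc, 1694 ± 382 in siAgo3 and 1191 ± 350 in siVret, miR-276 at 7.93 ± 0.155, 52.3 ± 14.5 and 28.2 ± 16.3, and miR-184 at 59.6 ± 2.13, 81.3 ± 22.5 and 58.2 ± 11.5.

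**Figure D2:**
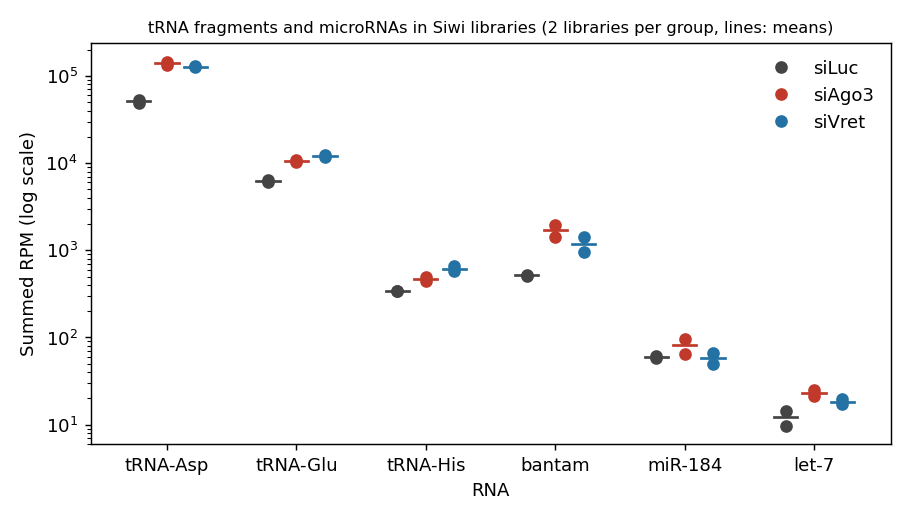
Summed RPM (y axis, log scale) of tRNA fragments and microRNAs (x axis) in the Siwi libraries of siLuc, siAgo3 and siVret. Points are libraries and lines are means of 2; tRNA-Asp, tRNA-Glu and bantam lie higher in every knockdown library than in both siLuc libraries, and miR-184 overlaps in siVret.

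Ago3 held RNAs with another signature than Siwi. Of the 407838 reads of the single Ago3_piRNA library, 89.4% were of 22 to 32 nt (95% Wilson interval 89.4 to 89.5%). Of these, 29.6% began with U (29.4 to 29.7%) and 58.7% had A at position 10 (58.5 to 58.8%), against 81.0% ± 0.598 and 32.2% ± 0.121 in Siwi of siLuc. Intervals from reads cover counting error only. Mean length was 26.8 nt. The most abundant Ago3-bound sequence, AGAAGCCGAACTGTGCAGCCCTTATGC, reached 21104 RPM in that library and 63.0 RPM ± 13.2 in Siwi of siLuc, where it fell to 40.9 ± 4.27 in siAgo3 (adjusted p = 0.041) and rose to 140 ± 5.50 in siVret (adjusted p = 0.0002123). GACTCGCGGATGTGGAGGCCATGCCC (9680 RPM with Ago3) was at 27.01 RPM ± 1.82 in Siwi of siLuc and rose to 54.8 ± 13.4 in siAgo3 and 144 ± 16.1 in siVret. ACAAGACTTCTCAGATCTAACCGCAGC (9283 RPM) rose from 40.7 ± 0.745 to 86.9 ± 22.7 and 145 ± 0.677, and TTCGGCTTCTCTTTTCATGAATTTTTCAAA (11566 RPM) fell from 220 ± 13.6 to 149 ± 31.0 and 147 ± 15.8. Sequences found in both the Ago3 library and Siwi of siLuc numbered 12440 and made up 59.6% of Ago3-bound RPM of that length and 12.2% of Siwi-bound RPM. Their abundances correlated weakly across sequences (Spearman rho = 0.261, Pearson r = 0.294 on log2 values), and among the 1930 with a mean of at least 20 RPM rho was -0.44, where the cut on the mean itself pulls rho down. The tables were normalised separately, so levels across them are shares of different totals.

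The ping-pong relation between the proteins was measured by sequence, since no genome positions were used. A Siwi-bound RNA was counted as paired when the reverse complement of its first 10 nt began an Ago3-bound RNA. This measure was chosen after the data were seen. The paired share was 19.4% ± 0.137 of RPM in siLuc, 15.2% ± 0.0469 in siAgo3 and 18.8% ± 0.106 in siVret. Left without tRNA fragments, it was 20.6% ± 0.0926, 17.9% ± 0.160 and 21.9% ± 0.148, which places siVret above siLuc in place of below it. For overlaps of 11 to 20 nt, the same first 10 nt were matched to bases further inside the Ago3-bound RNA. These overlaps gave 3.62 to 6.36% in siLuc without tRNA fragments. Most of these were higher in siVret as well, such as 11 nt (6.20% in siLuc, 6.21% in siAgo3 and 7.19% in siVret) and 18 nt (4.01%, 4.46% and 5.23%), so the higher share in siVret than in siLuc or siAgo3 was not specific to the 10-nt overlap. From siLuc to siAgo3 these other overlaps went both ways, such as 6.36% to 5.48% at 19 nt and 3.62% to 3.99% at 16 nt. Sequences with an Ago3-bound partner stood higher as a set in siVret than in siAgo3, with 926 higher and 311 lower of 4228, a median of 0.34 against 0.11 for other sequences, and an adjusted p of 0.023 (0.0465 with an estimated correlation). In siAgo3 against siLuc this set did not stand apart (328 higher, 868 lower; adjusted p = 0.58 and 0.28 with an estimated correlation). In siVret against siLuc the whole set did not pass either (907 higher, 775 lower; adjusted p = 0.156 and 0.091 with an estimated correlation). The 1790 sequences whose partner reached 20 RPM stood higher in siVret than in siLuc (471 higher, 303 lower; adjusted p = 0.0234 and 0.0329 with an estimated correlation). Shares paired with such partners were again higher at other overlaps too, from 0.806% in siLuc to 1.29% in siVret at 12 nt and from 0.700% to 1.20% at 16 nt, against 8.07% to 9.74% at 10 nt. In siAgo3 such shares, without tRNA fragments, fell only at 10 nt, to 7.38%. They rose at every overlap of 11 to 20 nt, such as to 0.919% at 12 nt and 0.830% at 16 nt. With tRNA fragments counted, the shares at 11, 14 and 19 nt fell as well, from 1.09% to 1.04%, 0.690% to 0.644% and 0.587% to 0.575%. As a set, the 1790 sequences did not stand apart by camera in siAgo3 against siLuc (182 higher and 346 lower). Their median was -0.12 against -0.15 for other sequences (adjusted p = 0.94, and 0.72 with an estimated correlation). Fry, which does not compare with other sequences, called them lower on RPM (adjusted p = 0.00189).

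**Figure D3:**
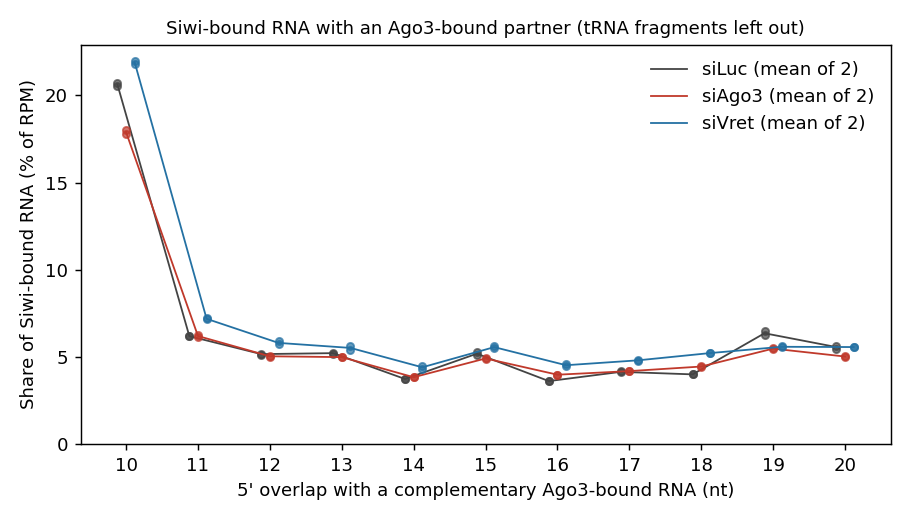
Share of Siwi-bound RPM (y axis, percent, tRNA fragments left out) whose first 10 nt are complementary to an Ago3-bound RNA at a 5′ overlap of 10 to 20 nt (x axis). At 10 nt the match is to the start of the Ago3-bound RNA, and at longer overlaps to bases further inside it. Points are libraries and lines are means of 2 per group; at 10 nt siVret lies at 21.9%, siLuc at 20.6% and siAgo3 at 17.9%.

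Target_L and Target_S asked which transposable elements supplied the longer and the shorter RNA in the Ago3 complex. Both pools were led by LTR retrotransposons, above all Pao, with 25.8% of Target_L and 19.95% of Target_S. Kabuki held 10.9% and 4.53%, the Pao-type LTR element Yamato 4.97% and 8.80%, the DNA element BmpiggyBac-MER85 5.41% and 4.80%, the Pao-type LTR element Noguchi 4.64% and 1.88%, and BmRT3 4.19% and 2.90%. Of the elements listed, 8 were among the 10 highest of both pools, and the top 10 made up 66.9% of Target_L and 49.1% of Target_S. Kokubaru, a Pao-group LTR element, was 7th in Target_S with 1.73% and held 0.292% of Target_L. At the other end, robertson-mariner held 1.10% of Target_L and 0.123% of Target_S, and Bmhopper 2.70% and 0.697%. Each pool is 1 library given in percent with unknown depth, so no replicate check, interval or test of any single element was possible.

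By class, 28 LTR elements made up 60.8% of Target_L and 52.7% of Target_S, and 29 non-LTR elements 12.6% and 19.4%. The 9 elements named TRAS or SART, retrotransposons that insert at silkworm telomere repeats, were all higher in Target_S, with 0.748% of Target_L and 3.61% of Target_S, and their median log2 ratio of 4.24 stood at the 96.8th percentile of 10000 random lists matched on mean level. On the same scale non-LTR elements stood at the 94.3rd, LTR elements at the 40.6th, SINE elements at the 7.88th and DNA elements at the 4.11th percentile, so several classes lay near an end. SART1 went from 0.632% to 1.31%, TRAS1 from 0.0467% to 0.883% and TRAS3 from 0.0357% to 0.854%. The 8 DNA elements made up 8.23% and 6.53%, and the 8 SINE elements 2.09% and 1.91%. The names of 48 further elements gave no class. These made up 16.2% of Target_L and 19.5% of Target_S, with a median log2 ratio of 2.70 (68.6th percentile). Across all elements the pools correlated with a Spearman rho of 0.796 (Pearson r = 0.806 on log2 values), with elements not being independent replicates. A total of 38 elements were over 10 times higher in Target_S and 8 were over 2 times higher in Target_L.

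**Figure D4:**
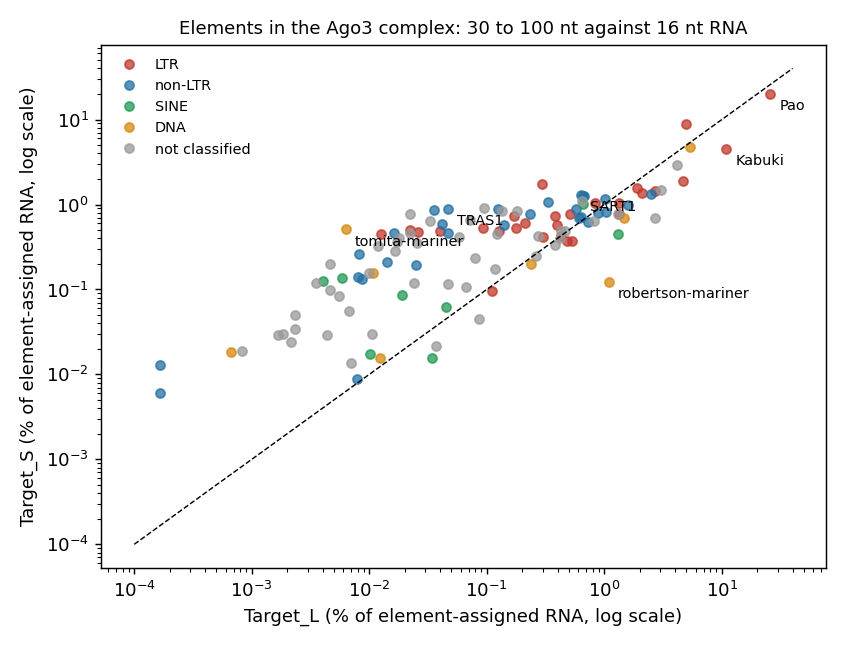
Share of each element in Target_S (y axis, percent, log scale) against Target_L (x axis, percent, log scale), coloured by class, with 1 library per axis. The dashed line marks equal shares; 89 elements lie above it, and Pao, Kabuki and robertson-mariner lie below.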

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

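The tests of tRNA fragments, of the most abundant sequences and of Target_S below were chosen after the results were seen; those of size selection were set before.

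Reads outside the main comparisons lie in the Ago3_piRNA library, where 10.5% of reads (42928 of 407838) are shorter than 22 nt, a length range absent from the Siwi table. Reads of 13 to 18 nt make up 6.43%. Of these, 25.2% (Wilson interval 24.7 to 25.8%) lie within an Ago3-bound RNA of 22 to 32 nt, most of them at its start (22.5%), 9.09% are complementary to one, and 0.111% match after their bases are shuffled.

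Siwi-bound RNAs that share a 5′ end were shorter in both knockdowns. If a different gel or bead size selection had weighted every RNA of a length alike, each family's ratio of 29-nt to 28-nt forms would move by the same factor. Over 488 families the variance of that change was 2.21 times what replicate differences give in siAgo3 (bootstrap interval 1.86 to 2.64) and 3.98 times in siVret (3.34 to 4.75), which argues against such a shift as the whole cause, although a part shared by all families (median -0.48 and -0.62 on the log2 scale) could still be technical. A few abundant sequences do not account for the fall in mean length of the whole Siwi pool. The difference from siLuc was -0.470 nt in siAgo3 and -0.417 nt in siVret without the 100 most abundant ones, and -0.485 and -0.432 nt with them. Lengths within families were not recomputed without those sequences. A change in 3′ end formation after loss of Ago3 or Vret remains an open, untested explanation, and library making by group cannot be separated from the knockdowns.

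Fragments of tRNA-Asp rose in both knockdowns. A lower piRNA yield that raised every other RNA alike would lift tRNA-Asp and tRNA-Glu equally, yet tRNA-Asp rose by 0.69 ± 0.0963 (SE) more on the log2 scale in siAgo3 and by 0.36 ± 0.0976 more in siVret. The shift to shorter RNA would lower a 29-nt fragment, yet in siAgo3 the 29-nt tRNA-Asp fragments rose by 1.72 ± 0.106 more than all other 29-nt sequences. The rise may still come from a lower piRNA share, in part or in whole. The microRNA list matched over 18 nt was higher by about as much (3.15-fold in siAgo3 and 2.23-fold in siVret). Bantam, at 3.29-fold and 2.31-fold, made up most of that list (515 of 605 RPM in siLuc). In the same order, miR-276 was at 6.60-fold and 3.56-fold, miR-184 at 1.36-fold and 0.977-fold, and miR-1 (4.11 RPM in siLuc) at 0.790-fold and 0.643-fold. With microRNAs so unequal, the gap between tRNA-Asp and tRNA-Glu decides nothing about a share that raises RNAs unequally. Loading of more tRNA fragments into Siwi is a hypothesis that these tables leave open.

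Full-length LTR elements that are rare in Target_L hold similar shares of Target_S, which does not extend to all rare elements, since 16 of the 53 under 0.05% in Target_L are under 0.05% in Target_S too. Chance matches of RNAs of about 16 nt, in proportion to the length of an element, could give such a floor. In the 7 full-length LTR elements under 0.2% in Target_L, Target_L ran from 0.0125 to 0.177% and Target_S only from 0.456 to 0.732%, a log2 range 0.179 times as wide. These elements were chosen for that pattern and few names give a length, so the range decides nothing. Among the 53 elements under 0.05% in Target_L, 29 were set apart by hand-picked words in their names, such as partial, MITE, Bm1, W and other-repeats. Only some of these words mark a short element, and an LTR element was among the 29. Their median was 0.0298% of Target_S against 0.430% for the other 24 (ratio 14.4, permutation p = 2e-05), and the ratio in Target_L was 3.18. The names do not sort elements cleanly by length. Longer elements would also give more true short products, so chance matches cannot be told apart from these.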

How the results depend on the processing

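The alternatives without tRNA fragments, with Ago3-bound partners of at least 20 RPM and with 1 siLuc library per knockdown were chosen after the results were seen. Among 676 values with a library left out 652 kept their reading, as did 543 of 580 under other settings. Some of these could not change, so the counts overstate stability. Leaving out a siVret library does not alter the siAgo3 against siLuc class medians, and rescaling does not alter a rank correlation. Every alternative to the correlation of fold changes moved it by more than the spread between simulations. Calls in siAgo3 against siLuc, siVret against siLuc and siVret against siAgo3 numbered 3044, 4199 and 2367 with no filter, 2577, 3164 and 2513 at 20 RPM, and 5732, 8060 and 5949 with a replicate block, although replicate numbers pair no libraries (correlations of replicate differences -0.00181, 0.0547 and 0.0236). With a library left out they ran from 2213 (siLuc replicate 1) to 5823 (siVret replicate 1), from 4040 (siLuc replicate 1) to 8438 (siAgo3 replicate 2) and from 3319 (siAgo3 replicate 2) to 5009 (siAgo3 replicate 1). The single class called in siVret against siAgo3 became 2 at 20 RPM, 0 without siAgo3 replicate 2 and stayed 1 without siLuc replicate 1. The correlation of fold changes was 0.673 at 20 RPM, 0.626 with a pseudocount of 5 RPM, 0.512 and 0.515 with siLuc replicate 1 or 2 for siAgo3 and the other for siVret, and 0.527 (without siAgo3 replicate 1) to 0.620 (without siLuc replicate 2) with a library left out. The first-base U difference from siLuc, in points for siAgo3 and siVret, was -2.60 and -2.18 with each sequence counted once, -2.86 and -2.59 without the 100 most abundant, and -2.07 and -2.30 without tRNA fragments, which reversed its sign in siAgo3. That of A at position 10 was -0.174 and -0.922, -0.0349 and -1.22, and -0.598 and -1.64 in the same order, and -3.08 and -3.64 at 24 to 32 nt. Mean length in siAgo3 differed by -0.358 nt at 24 to 32 nt. The Ago3-partner share differed by -2.73 and 1.27 points without tRNA fragments, -1.33 and 0.768 with partners of at least 20 RPM, and -3.93 and -0.162 at 24 to 32 nt, so its direction in siVret is open. The microRNA list differed by 1305 and 747 RPM over 18 nt. Ago3-bound and Siwi-bound levels had a rho of -0.44 at 20 RPM.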

Other observations

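Sequences confined almost to 1 group are described here by length and base content, without a test. With a minimum of 5 RPM in both libraries of a group and at least 10 times every other library, a rule set after the data were seen, 137 sequences stood out in siLuc, 35 in siAgo3 and 7 in siVret. Those of siLuc were long, 127 of them of 30 nt or more, and summed to 4628 RPM ± 209 against 196 ± 30.5 in siAgo3 and 213 ± 25.2 in siVret. Those of siAgo3 had a mean length of 24.8 nt and none reached 30 nt. They were 38.1% A, where the sequences of the whole table average 27.9%, and summed to 665 RPM ± 89.4 in siAgo3, 0.908 ± 0.231 in siLuc and 10.5 ± 0.464 in siVret. The largest rises in siAgo3 fell into a few overlapping families, so these sequences are not independent. Their A content may be that of few RNAs. The origin of the siAgo3 sequences is not assigned here. The rule itself sets the gaps between groups in these sums. Counts of the groups are not on an equal footing either, since 1 read is worth 1.65 RPM in siAgo3 replicate 2 and 0.372 RPM in siLuc replicate 1.

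The Siwi pool differed between groups in how many kinds of RNA it held. In 600000 reads drawn from each library, 174003 and 175173 distinct sequences were found in siLuc, 193238 and 190497 in siAgo3, and 146164 and 147761 in siVret. RNAs identical to an Ago3-bound one made up 12.2% ± 0.113 of Siwi-bound RPM in siLuc, 10.1% ± 0.0162 in siAgo3 and 13.6% ± 0.0708 in siVret. AGAAGCCGAACTGTGCAGCCCTTATGT, at 9420 RPM with Ago3, was not among the sequences listed for Siwi. The Siwi and Ago3 lists may cover different kinds of sequence, so this does not show that Siwi lacked it. A near-identical sequence led the Ago3 library and was present in every Siwi library.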
